A study of Homo sapiens with 8 samples.

How the data were processed

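Gene expression was measured in primary human keratinocytes with 8 single-colour Affymetrix arrays, in 4 groups of 2 arrays each. Cells carried a control shRNA, an shRNA against SNAI2, a LacZ expression construct or a SNAI2 expression construct, per the labels. The values deposited by the authors are probe set signals on a linear intensity scale, from 1 table for all arrays. They were made with Affymetrix Expression Console, per the submitters' processing notes; its version and the algorithm that combined the probes are not given in the sources used here. The scale of the deposited intensity values differed between the experiments: by the 2% trimmed mean, the LacZ and SNAI2 construct arrays were 1.93 times as bright as the shRNA arrays. Each perturbation was therefore compared with its own control.

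The table holds 54675 probe sets, of which 62 are array controls. Gene names came from the platform's probe table, in which 41091 probe sets name 1 gene, 1801 name several and 11721 name none; no symbol needed updating against the reference gene table. Probe sets naming several genes or none were left out of the gene tests. For each of the 19740 genes, the probe set with the highest mean over the 8 arrays was used. Genes in the lowest 25% by mean level were left out, which kept 14805 genes. XIST and genes of the Y chromosome were left out of all gene tests, but not of the array-wide signal summaries and scalings. Values were taken as log2(value + 16), so fold changes are on that scale, which understates the change of genes with low signals.

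Tests used limma 3.58.1 in R 4.3.3. lmFit fitted 1 mean per group to all 8 arrays, since sharing the spread among the 4 groups left 4 residual degrees of freedom, and eBayes moderated the spread, with 3.84 prior degrees of freedom. Tests were two-sided, and a gene passed at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. The contrasts were SNAI2 shRNA minus control shRNA, SNAI2 construct minus LacZ, the difference between these, and LacZ minus control shRNA. Counts of genes that also changed at least 2-fold are given beside the main counts. Genes past the threshold in both comparisons were set against the product of the 2 counts divided by the genes tested, with Fisher's exact test across genes as a description, because genes are not independent replicates. No arrays are shared between the comparisons. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

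The main design, the alternatives other than those named below as added, the gene lists and the rule for naming genes were fixed before the data were examined. There are 20 lists with 597 genes, of which 534 were measured and 477 tested; 4 genes stand in 2 lists each. The lists hold cornified envelope, skin barrier lipid, desquamation protease, differentiation regulator, basal layer, DNA replication, G2/M and mitosis, wound and antimicrobial, inflammatory cytokine, interferon-stimulated, p53 target, epithelial junction, mesenchymal, matrix and migration, immediate early, cholesterol synthesis and unfolded protein genes. The remaining lists hold markers of fibroblasts, of melanocytes, and of leukocytes and endothelium. Each list was tested with camera at a preset correlation of 0.01, adjusted over the 20 lists of a comparison, and again with an estimated correlation and with fry. Unlike camera, fry does not set a list against the other genes. Named genes were the 10 highest and 10 lowest of each main comparison among genes past the threshold whose arrays did not overlap between the groups, up to 4 members per list with the largest changes, and a fixed set of keratinocyte genes. The rule also took, among genes changed in opposite directions, the 10 per direction whose smaller change of both comparisons was largest, and the 5 highest and 5 lowest genes between the controls. From that last set, 1 gene whose level can reflect an inherited trait is not reported here. List members named outside this rule were chosen after their values were seen.

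The fit was tested on simulated arrays with the real genes' means. The genes' spreads were reassigned at random among them, and the noise was independent between genes. Per comparison, 67, 67 and 66 genes were changed by 0.5, 1 and 2 on the log2 scale. That share is far below the 44.3% and 48.5% of genes called in the data, so recovery in the data may differ. Simulated for the shRNA comparison over 14805 genes, 61.2%, 92.5% and 100% of genes changed by 0.5, 1 and 2 on the log2 scale were recovered, with 14 false among 183 calls. For the construct comparison these shares were 70.1%, 98.5% and 98.5%, with 7 false among 185 calls. A list raised by 0.5 was the only 1 of 20 lists called by camera. Genes of a list did not vary together in the simulated arrays, so this does not test the preset correlation on real lists.

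Alternatives covered the pseudocount (1 and 64), the filter on dim genes, quantile normalization, median centring, other eBayes priors, fits to only the 4 arrays compared, other uses of several probe sets per gene, stricter thresholds, a replicate block and leaving out each array in turn. Scaling each array by its trimmed mean and a crossed pairing of the construct arrays were added after seeing the data. Another background correction was not run, because it needs probe-level values, which were not used here. No genome build is named for the values, so no coordinates are given. The number of arrays limits the precision of every value.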

Results

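The study asked how gene expression in keratinocytes, the epithelial cells of the epidermis, changes when SNAI2 is lowered or raised. SNAI2, also called Slug, is a zinc finger transcription factor known as a repressor of epithelial genes. An shRNA, a short hairpin RNA that lowers the transcript it targets, was set against a control shRNA, and a SNAI2 expression construct against a construct for LacZ, a bacterial gene used as a control. Each of the 4 groups had 2 arrays. The median signal was 20.9 to 21.8 on the shRNA arrays and 42.5 to 43.6 on the construct arrays. Across all genes, the arrays of a group correlated at r = 0.996 to 0.998. The labels do not say that replicates came from separate cultures or donors, so p-values measure only the spread between these arrays, which may be technical. Values are mean signal ± SD with n = 2, and changes are differences of log2(value + 16) with the SE from limma.

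The SNAI2 transcript was measured by 1 probe set, 213139_at. In the control shRNA arrays its signal was 2517 and 2884, and in the SNAI2 shRNA arrays it was 2005 and 1916. It fell by 0.46 on the log2 scale (SE 0.0757, adjusted p = 0.00169, 1.37-fold). In the LacZ arrays the signal was 5098 and 4992, and in the arrays labelled SNAI2 overexpression it was 2464 and 2588. There it fell by 0.99 (SE 0.0757, adjusted p = 2.13e-05, 1.99-fold), opposite to the label. Which part of the transcript the probe set reads is not known here, so it was not used to check whether the construct was expressed. Directions below follow the labels, and the construct group is called the arrays labelled SNAI2 overexpression throughout.

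**Figure D1:**
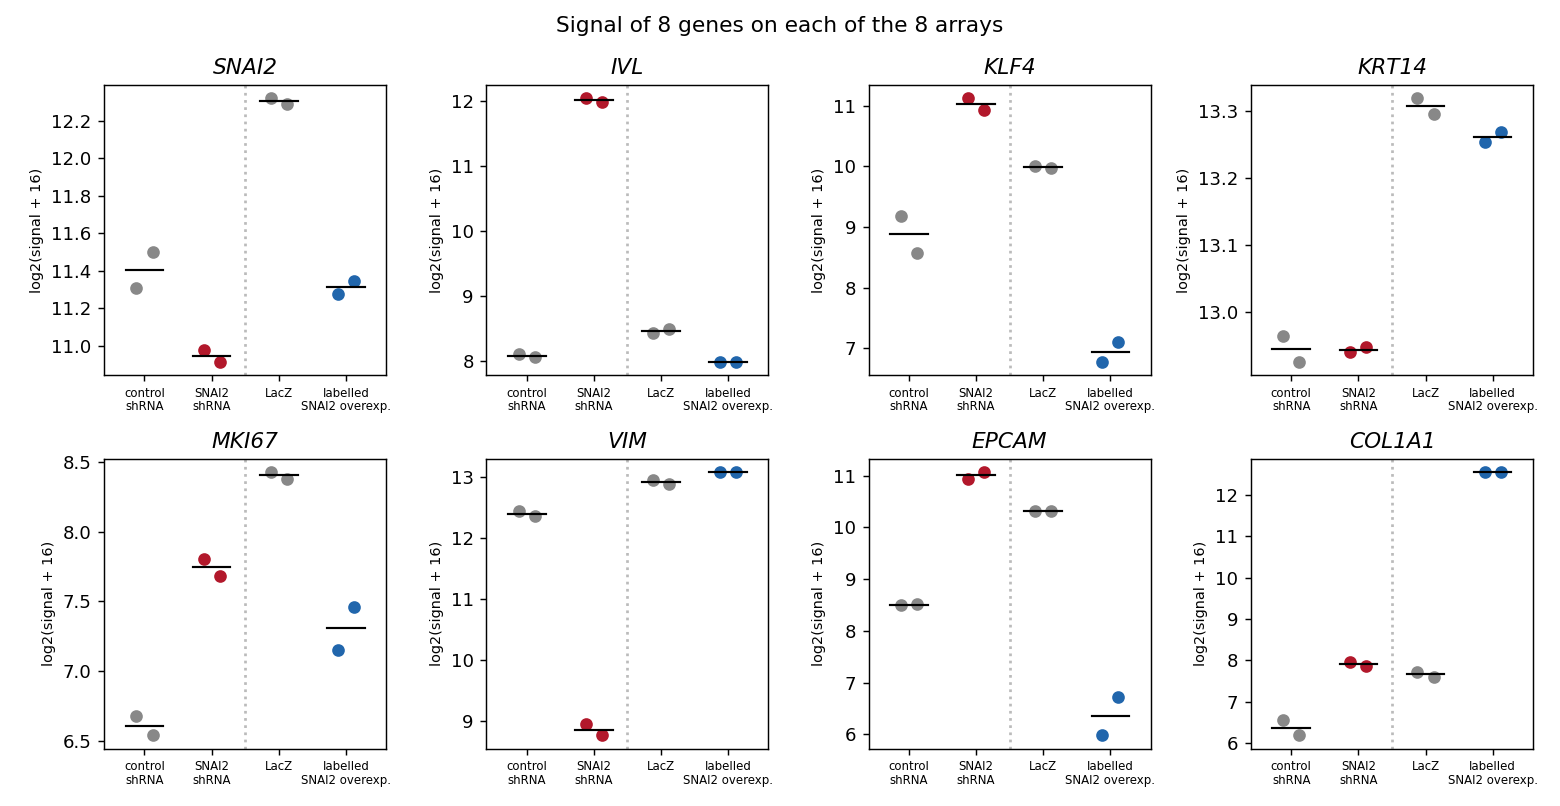
Signal of 8 genes on each of the 8 arrays, on a log2(signal + 16) axis that does not start at 0 and differs between panels. Each dot is 1 array, the black line is the mean of 2 arrays, and the dotted line separates the shRNA from the construct experiment, which have different scales. SNAI2 lies lower in both SNAI2 groups than in their controls (1960 against 2700 and 2526 against 5045), while KRT14 differs by less than 0.05 in each experiment.

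In the SNAI2 shRNA arrays 27 of 29 cornified envelope genes were higher than in the control, and 21 of 27 mesenchymal and 33 of 36 interferon-stimulated genes were lower. These lists passed by camera at its preset correlation but not with an estimated correlation (adjusted p = 0.0548, 0.0541 and 0.122). KRTDAP and SBSN, secreted proteins of differentiating epidermis, rose by 5.65 (SE 0.173) and 5.10 (SE 0.105), from 93.1 ± 33.8 to 5315 ± 74.7 and from 102 ± 20.2 to 4014 ± 140. IVL, a precursor protein of the cornified envelope, rose 15.4-fold from 253 ± 5.89 to 4127 ± 120, and TGM1, the transglutaminase that cross-links the envelope, rose 17.6-fold. VIM, an intermediate filament protein of mesenchymal cells, fell by 3.54 (SE 0.0744), from 5371 ± 206 to 447 ± 42.9, and its other probe set fell by 1.03. Of the 14805 genes tested, 6553 changed, 3020 upward and 3533 downward, and 871 changed at least 2-fold, 552 upward and 319 downward.

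The other genes with the largest rises were PPBP, a chemokine precursor (50.5-fold), DSG1, a desmosomal cadherin (from 0.865 ± 0.954 to 549 ± 16.4), SPRR2G (31.6-fold), CNFN (30-fold), TMEM45B (27.8-fold), SERPINB3 (27.2-fold), LCE3D (25-fold) and the amino acid transporter SLC6A14 (24.9-fold). The probe sets of PPBP, SPRR2G, CNFN, SERPINB3 and LCE3D carry the endings of sets whose probes can match several transcripts, so related copies of these genes could add to their signal. The largest falls, besides that of VIM, were those of the adhesion molecule L1CAM (13-fold), the matrix proteoglycan VCAN (11.5-fold), CYGB (11.2-fold), NEFL (10.3-fold), TGM2 (10.3-fold), the hyaluronan synthase HAS2 (9.98-fold), CDH11 (8.55-fold), MSRB3 (7.51-fold) and SYNPO (7.19-fold). In this comparison the lower group of DSG1, CEBPA, IL36RN, FA2H, SDR9C7, NR4A2, PADI3, VCAN, GLT8D2, C3, POSTN, CSF3 and COL6A1 had a mean signal under 16, so the size and rank of their changes depend on the pseudocount (DSG1 5.07, and 3.24 at pseudocount 64). At least 1 other probe set did not fall for NEFL (up to 0.01), XAF1 (0.03), TGM2 (0.05), CYGB (0.06), MMP2 (0.19), POSTN (0.20) and CD44 (0.35). For other named genes the weakest probe set kept the direction but moved far less than the one used. Among these were SYNPO (-0.11), ADAM19 (-0.10), TP53INP1 (-0.08), FA2H (0.36) and OVOL1 (0.81).

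Among cornified envelope genes, 27 of 29 rose and 2 fell, KRT10 by 0.30 (SE 0.0571) and PADI3 by 0.22. LORICRIN rose by 0.36 (SE 0.105, adjusted p = 0.0236), a call lost without SNAI2 shRNA replicate 1 or without either control array (adjusted p = 0.107, 0.102 and 0.0605). KRT1 and FLG lay below the level filter, and in a fit of all genes they rose (adjusted p = 0.000122 and 0.000274) at signals of at most 36.8 and 37.4, where the size of a change depends on the pseudocount. Of the kallikreins, other proteases and inhibitors of the upper epidermis, 21 of 22 rose and 1 did not pass, with KLK11 up 10.9-fold, KLK7 10.3-fold and SERPINB13 7.71-fold. Of the skin barrier lipid genes, 10 of 16 rose, 3 fell and 3 did not pass; the lipid transporter ABCA12 rose 14.7-fold, SULT2B1 14.2-fold, SDR9C7 9.5-fold and FA2H 6.74-fold. Of these lists, 29, 22 and 13 members passed when adjusted over the list alone. Their camera tests gave adjusted p = 2.58e-18, 1.63e-17 and 0.000145, and adjusted p = 0.0548, 0.0548 and 0.0788 with an estimated correlation.

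Regulators of epidermal differentiation rose in 17 of 27 cases, fell in 2 (JAG1 and NOTCH1) and did not pass in 8. The homeodomain protein HOPX rose 24.1-fold, CEBPA 18.3-fold, ZNF750 18.1-fold, GRHL1 17.8-fold, OVOL1 10.7-fold, GRHL3 8.86-fold and KLF4 4.43-fold, the last from 466 ± 142 to 2076 ± 199. Epithelial junction genes rose in 27 of 30 cases, with DSG2 lower and 2 not past; NECTIN4 rose 10-fold, OCLN 8.58-fold, EPCAM 5.66-fold, CLDN4 4.73-fold, though its other probe set gave -0.14, and CDH1, encoding E-cadherin, 1.26-fold. Stress keratins and antimicrobial proteins rose in 11 of 15 cases, fell in 2 and did not pass in 2, with PI3 up 22.5-fold, DEFB1 14.3-fold, S100A7 11.2-fold and S100A9 8.61-fold, while the complement gene C3 fell by 2.24. In these lists 20, 29 and 14 members passed when adjusted over the list alone. Their adjusted p values were 5.97e-07, 2.49e-12 and 1.57e-06 by camera, and adjusted p = 0.129, 0.12 and 0.0588 with an estimated correlation.

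Cell cycle genes were higher in the same arrays. All 38 G2/M and mitosis genes rose, with a median change of 1.12, among them DLGAP5 (2.65-fold), CCNA2 (2.55-fold), TOP2A (2.54-fold), KIF2C (2.51-fold) and MKI67 (2.2-fold, SE 0.106 on the log2 scale). DNA replication genes rose in 33 of 34 cases, with 1 not past, including MCM10 (2.68-fold), POLE2 (2.37-fold) and CDC6 (2.28-fold). GINS2 rose 2.55-fold by its brightest probe set, and its other probe set gave -0.05 (adjusted p = 0.621). When adjusted over the list alone all 38 G2/M members passed, and of the 34 replication members 33 passed as higher and RFC5 as lower (-0.40). The camera tests gave adjusted p = 1.34e-20 and 2.13e-15, and adjusted p = 0.139 and 0.147 with an estimated correlation.

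Mesenchymal genes fell in 21 of 27 cases, 1 rose and 5 did not pass; besides VIM and CDH11, the microfibril protein FBN1 fell 5.72-fold and the gelatinase MMP2 4.98-fold. Matrix and migration genes fell in 17 of 26 cases, rose in 3 and did not pass in 6, with ADAM19 down 3.78-fold, the plasminogen activator PLAT 3.64-fold, CCN2 2.99-fold and ADAMTS1 2.65-fold. Of 36 interferon-stimulated genes, 33 fell, 0 rose and 3 did not pass; those that fell included IFIT3 (3.88-fold), XAF1 (3.78-fold), MX2 (3.09-fold) and ISG15 (2.99-fold). Of 25 p53 target genes, 15 fell and 10 did not pass, with XPC down 1.8-fold, TNFRSF10B 1.69-fold and TP53INP1 1.62-fold. FAS fell 2.04-fold by its brightest probe set, but without sets whose probes can match several transcripts it gave -0.09 (adjusted p = 0.52). Basal layer genes fell in 19 of 26 cases, rose in 4 and did not pass in 3, with POSTN down 2.87-fold, CD44 1.64-fold, CAV1 1.61-fold and BCAM up 1.73-fold. The integrin ITGB1 fell 1.18-fold, a call lost without SNAI2 shRNA replicate 1 or control shRNA replicate 2 (adjusted p = 0.072 and 0.101). When adjusted over the list alone, 24, 20, 33, 16 and 23 members passed. By camera the adjusted p values were 2.07e-10, 0.000152, 2.26e-16, 0.000152 and 0.00102, and adjusted p = 0.0541, 0.0639, 0.122, 0.122 and 0.147 with an estimated correlation. The basal keratin KRT14 differed by -0.001 (SE 0.053, adjusted p = 0.989), and KRT5 by 0.16 (SE 0.0562, adjusted p = 0.0464, above 0.05 without any 1 of the 8 arrays).

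Immediate early genes rose in 10 of 25 cases, fell in 2 and did not pass in 13, with EGR3 up 4.29-fold, ZFP36 2.45-fold and DUSP2 1.7-fold, and NR4A2 at 1.96-fold (adjusted p = 0.0316), which was lost without SNAI2 shRNA replicate 1, either control shRNA array or either array labelled SNAI2 overexpression, with adjusted p up to 0.133. When adjusted over the list alone 12 passed, and camera gave adjusted p = 0.0186, and adjusted p = 0.566 with an estimated correlation. The other lists did not pass by camera. Inflammatory cytokine genes rose in 6 of 27 cases and fell in 11 (adjusted p = 0.288 for a lower list, while fry pointed upward at adjusted p = 0.479), with IL36RN up 15-fold and CXCL5 down 2.89-fold and CSF3 lower at a signal near 0 (32.8 ± 5.05 in the control). Cholesterol synthesis genes rose in 6 of 19 cases and fell in 2 (adjusted p = 0.143), with TM7SF2 up 3.47-fold, PMVK up 1.42-fold and LSS down 1.43-fold, and 5 members passed without control shRNA replicate 1. Unfolded protein genes rose in 3 of 26 cases and fell in 9 (adjusted p = 0.27), counts that were 0 and 4 without control shRNA replicate 1 and 1 and 6 without SNAI2 shRNA replicate 2; HERPUD1 fell 1.57-fold. Of the members of these lists, 17, 8 and 15 passed when adjusted over the list alone. Among markers of other cell types, 3 of 16 fibroblast markers rose and 5 fell (adjusted p = 0.453), including COL1A1 up 2.92-fold and FAP down 1.59-fold; the list's median was 0.004 and its mean -0.14. For COL6A1 the brightest probe set fell 2.22-fold, and without sets matching several transcripts it gave -0.13 (adjusted p = 0.247). Of 9 melanocyte markers, 2 rose and 2 fell (adjusted p = 0.664), with RAB38 up 1.88-fold, and 2 in all passed without SNAI2 shRNA replicate 1 or control shRNA replicate 1. Of 8 leukocyte and endothelial markers, 1 rose, CD3D (1.22-fold, adjusted p = 0.0482), at signals of 17.2 ± 2.48 and 24.4 ± 1.85 near the dim end of the arrays (adjusted p = 0.0547 to 0.233 without any 1 of the 4 shRNA arrays or the 2 LacZ arrays, each of which left 0 markers or a different one past the threshold). Adjusted over the list alone, 8, 4 and 0 members of these marker lists passed.

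By camera with its preset correlation, 14 of 20 lists passed in this comparison. With an estimated correlation, camera called 0 of 20, with 8 at an unadjusted p under 0.05 and the lowest adjusted p = 0.0541, while fry called 17. With 2 arrays per group, leaving out any 1 array left between 4911 and 6541 genes past the threshold.

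The arrays labelled SNAI2 overexpression, set against LacZ, showed higher mesenchymal genes, fibroblast markers and inflammatory cytokine genes as lists, and lower epithelial junction genes and desquamation proteases. These calls hold at camera's preset correlation and were lost with an estimated correlation (adjusted p = 0.056, 0.056, 0.334, 0.154 and 0.154). Directions here rest on the labels, which the SNAI2 probe set does not bear out. COL3A1, a fibrillar collagen, rose from 1.88 ± 2.66 to 925 ± 8.78 (5.73 on the log2 scale, SE 0.108), and POSTN, a matrix protein, rose by 5.07 (SE 0.0573), from 114 ± 5.97 to 4351 ± 34.1. ZEB1, a repressor of epithelial genes, rose by 2.87 (SE 0.142), from 20.8 ± 2.73 to 254 ± 21.1. EPCAM, an epithelial adhesion molecule, fell by 3.96 (SE 0.199), from 1254 ± 0.856 to 68.3 ± 30.2, and CDH1 fell by 2.00 (SE 0.0662), from 5071 ± 169 to 1257 ± 86.8. In all, 7178 genes changed, 3739 upward and 3439 downward, and 1040 changed at least 2-fold, 543 upward and 497 downward.

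The other genes with the largest rises were LRRC17 (36.4-fold), COL1A1 (29.9-fold), the intermediate filament NES (29.5-fold), CLDN11 (26-fold), FABP4 (25.2-fold), the cytokine IL33 (24.9-fold), the basement membrane protein NID1 (23.3-fold) and CNIH3 (22.2-fold). For COL1A1, 4 of 5 probe sets rose and the lowest gave -0.62. Another probe set did not share the direction for LOXL2 (-0.01), NID1 (-0.03), OVOL1 (0.03) and MCM4 (0.33). The weakest probe set kept the direction but moved far less for POSTN (0.16), TGM2 (0.21), GRHL1 (-0.39) and ADAM8 (-0.10), among others. The lower group of COL3A1, LRRC17, NES, FABP4, CNIH3, COL1A2, SERPINB4, KRTDAP, LORICRIN, TGM1 and ZNF750 had a mean signal under 16, so the size and rank of their changes depend on the pseudocount. The other largest falls were MAL2 (14.2-fold), TPD52 (12.3-fold), RAB25 (11.5-fold), ADIRF (11.4-fold), the connexin GJB6 (10.8-fold), the chloride channel ANO1 (10.4-fold), GRHL2, a transcription factor of epithelial cells (10.4-fold), and the kallikreins KLK8 (10.2-fold) and KLK10 (9.3-fold).

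Epithelial junction genes fell in 26 of 30 cases, 1 rose (MUC1, by 0.53) and 3 did not pass, with a median change of -1.64; the splicing regulator ESRP1 fell 8.86-fold and ST14 8.36-fold. Mesenchymal genes rose in 21 of 27 cases, 2 fell (S100A4 and PRRX1) and 4 did not pass, with LOX up 13.3-fold, FBN1 9.26-fold and LOXL2 7.99-fold. Vimentin itself differed by 0.16 (SE 0.0744, adjusted p = 0.105), and the mean of both VIM probe sets rose by 0.80 (adjusted p = 3.2e-05). Markers of fibroblasts moved with these lists: 11 of 16 rose, 1 fell and 4 did not pass, with a median change of 2.24, and COL1A2 rose 21.7-fold. LUM and COL6A2, also in that list, differed by -0.03 (SE 0.0854) and 0.07 (SE 0.072). In the junction, mesenchymal and fibroblast lists, 27, 24 and 13 members passed when adjusted over the list alone. Their camera tests gave adjusted p = 7.22e-15, 1.51e-08 and 1.43e-06, and adjusted p = 0.154, 0.056 and 0.056 with an estimated correlation.

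Desquamation proteases and inhibitors fell in 17 of 22 cases, rose in 3 and did not pass in 2; KLK5 fell 9.08-fold and KLK7 7.97-fold, while SERPINB4 rose from near 0 to 219. Differentiation regulators fell in 16 of 27 cases, rose in 5 and did not pass in 6, with KLF4 down 8.26-fold from 1000 ± 13.5 to 108 ± 19.8, GRHL1 3.87-fold, OVOL2 3.79-fold, GRHL3 3.18-fold, ZNF750 1.94-fold and OVOL1 1.58-fold. Cornified envelope genes fell in 16 of 29 cases, rose in 4 and did not pass in 9, with PPL down 7.36-fold, SPRR1A 6.5-fold, SPRR1B 5.78-fold, LORICRIN 2.34-fold, TGM1 1.56-fold and IVL 1.38-fold. Stress keratins and antimicrobial proteins fell in 9 of 15 cases, 1 rose (C3, 2.82-fold) and 5 did not pass, with KRT16 down 4.73-fold, SLPI 4.07-fold and LCN2 3.33-fold. Basal layer genes fell in 13 of 26 cases, rose in 5 and did not pass in 8, with KRT15 down 6.6-fold, BCAM 5.41-fold, SOX7 3.8-fold and KRT5 1.41-fold, while KRT14 differed by -0.05 (SE 0.053, adjusted p = 0.513). ITGB1 rose 1.19-fold, a call lost without LacZ replicate 1 or replicate 1 labelled SNAI2 overexpression (adjusted p = 0.074 and 0.0628). KRT10 differed by 0.14 (adjusted p = 0.0725), and KRT1 and FLG, below the level filter, did not pass (adjusted p = 0.262 and 0.0675). Adjusted over the list alone, 20, 23, 20, 12 and 18 members passed. The camera tests gave adjusted p = 1.02e-07, 0.00123, 0.00132, 0.00132 and 0.0151, and adjusted p = 0.154, 0.334, 0.334, 0.154 and 0.334 with an estimated correlation.

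G2/M and mitosis genes fell in 35 of 38 cases, none rose and 3 did not pass, with a median change of -0.58; MKI67 fell 2.14-fold, KIF20A 1.86-fold and AURKB 1.66-fold. DNA replication genes fell in 28 of 34 cases and 6 did not pass, with RRM2 down 2.21-fold, CDT1 2.06-fold and MCM4 1.71-fold; without LacZ replicate 1, 18 passed. Inflammatory cytokine genes rose in 16 of 27 cases, fell in 6 and did not pass in 5, with CXCL5 up 12.5-fold from 409 ± 4.35 to 5300 ± 120, CXCL6 11.6-fold and CXCL8 8.43-fold. Of 25 p53 target genes, 11 rose, 3 fell and 11 did not pass, with GDF15 up 1.68-fold, XPC 1.67-fold and SESN1 1.56-fold and PMAIP1 down 1.84-fold. Adjusted over the list alone, 36, 29, 23 and 15 members of these lists passed. The camera tests gave adjusted p = 7.72e-11, 2.41e-07, 0.00123 and 0.0471, and adjusted p = 0.334, 0.367, 0.334 and 0.367 with an estimated correlation.

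Camera did not pass for the remaining lists. Interferon-stimulated genes were split, with 14 of 36 higher and 11 lower (adjusted p = 0.575), including BST2 up 3.35-fold and IFIH1 down 3.11-fold; without LacZ replicate 2, 16 members passed. Matrix and migration genes rose in 10 of 26 cases and fell in 6 (adjusted p = 0.338), with TIMP1 and CCN2 up 3.04-fold and 3.05-fold and ADAM8 down 5.39-fold. Immediate early genes rose in 7 of 25 cases and fell in 6 (adjusted p = 0.818), with KLF2 up 5.56-fold and DUSP4 down 2.14-fold; 8 passed without LacZ replicate 1 or without replicate 1 labelled SNAI2 overexpression. Skin barrier lipid genes rose in 3 of 16 cases and fell in 6 (adjusted p = 0.575), with fewer passing without either of those same arrays. SDR9C7 fell 2.27-fold, and SMPD1 rose 1.82-fold by its brightest probe set. Both SMPD1 probe sets above the level filter rose, by 0.67 and 0.86, but without sets that can match several transcripts SMPD1 gave -0.53 (adjusted p = 0.00505). Cholesterol synthesis genes rose in 7 of 19 cases and fell in 2 (adjusted p = 0.469), 5 passing without LacZ replicate 2, and unfolded protein genes rose in 11 of 26 cases and fell in 8 (adjusted p = 0.575). Of 9 melanocyte markers, 0 rose and 2 fell (adjusted p = 0.463), RAB38 by 1.07 and SOX10, whose other probe set rose, by 0.57. Of these markers 4 passed without replicate 1 labelled SNAI2 overexpression or either control shRNA array, and 1 without LacZ replicate 2 or replicate 2 labelled SNAI2 overexpression. SOX10 was lost without LacZ replicate 2 or replicate 2 labelled SNAI2 overexpression (adjusted p = 0.0655 and 0.0728). Of 8 leukocyte and endothelial markers, CD207 fell by 0.52 and 7 did not pass; 2 passed without replicate 2 labelled SNAI2 overexpression or without either SNAI2 shRNA array. Adjusted over the list alone, 27, 16, 13, 10, 9, 21 and 2 members of the lists from interferon to melanocyte passed.

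Over the 20 lists, 12 passed by camera in this comparison. With an estimated correlation, camera called 0 of 20, with 5 at an unadjusted p under 0.05 and the lowest adjusted p = 0.056, while fry called 14. The arrays labelled SNAI2 overexpression also had a 1.8-fold lower signal of the poly-A spike-in controls, RNA added before labelling, than the LacZ arrays (-0.85 over 24 probe sets), and leaving out any 1 array left between 5329 and 7527 genes.

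Both perturbations were then compared gene by gene, to see whether they mirror each other. KLK10, a kallikrein protease, rose by 2.55 (SE 0.0744) with SNAI2 shRNA and fell by 3.22 (SE 0.0744) in the arrays labelled SNAI2 overexpression. TGM2, a transglutaminase, fell by 3.36 (SE 0.0579) and rose by 2.38 (SE 0.0579). Of 4007 genes that changed in both comparisons, 3087 (77%) changed in opposite directions and 920 in the same direction. These shares follow the labels of the LacZ and SNAI2 overexpression arrays, and an exchange of those labels would turn opposite into same. Higher with SNAI2 shRNA and lower in the arrays labelled SNAI2 overexpression were 1412 genes, against 702 expected for independent lists, and 1675 changed the other way, against 892. Genes higher in both numbered 404 against 763 expected, and genes lower in both 516 against 821. Among 288 genes that changed at least 2-fold in both, 257 (89.2%) were opposite.

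Ranked by the smaller of both changes, the first genes that rose with SNAI2 shRNA and fell in the arrays labelled SNAI2 overexpression were KLK7, PPL, KRTDAP, KLK10, CRCT1, MAL2, EPCAM, A2ML1, NIPAL4 and CA2, with changes from 2.33 to 5.65 in the shRNA comparison and from -3.96 to -2.43 in the arrays labelled SNAI2 overexpression. Those changed the other way were HAS2, COL5A2, FBN1, TGM2, MMP2, ESM1, GLT8D2, PAPSS2, VCAN and ARHGEF40. The 3 ARHGEF40 probe sets above the level filter all fell with SNAI2 shRNA, the least by 0.58. Without sets that can match several transcripts, ARHGEF40 gave 0.12 (adjusted p = 0.549) in that comparison. By share of a list, opposite changes of the first kind were most frequent among G2/M genes (35 of 38), junction genes (24 of 30), replication genes (27 of 34), desquamation proteases (16 of 22), stress keratins and antimicrobial proteins (9 of 15) and cornified envelope genes (16 of 29). Mesenchymal genes moved the other way in 17 of 27 cases. In the same direction in both moved 9 interferon-stimulated and 8 basal layer genes, all lower, 5 immediate early genes that were higher, and 3 higher genes in each of the cornified envelope, desquamation protease and differentiation regulator lists. The other lists had at most 2 such genes in either direction.

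Across genes, the changes of the comparisons correlated at Pearson r = -0.356 and Spearman rho = -0.35, with genes not being independent replicates. The 8 other ways to regroup the arrays within the experiments gave r from -0.0423 to 0.135. Each of them puts a control and a SNAI2 array on both sides in at least 1 experiment. The group difference cancels there, so these values give no reference range for r = -0.356. In the test of the difference between the responses, 7960 genes passed, 3744 higher with SNAI2 shRNA relative to the arrays labelled SNAI2 overexpression and 4216 lower, and 14 of 20 lists passed by camera; with an estimated correlation 1 did, the mesenchymal list (adjusted p = 0.0429).

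**Figure D2:**
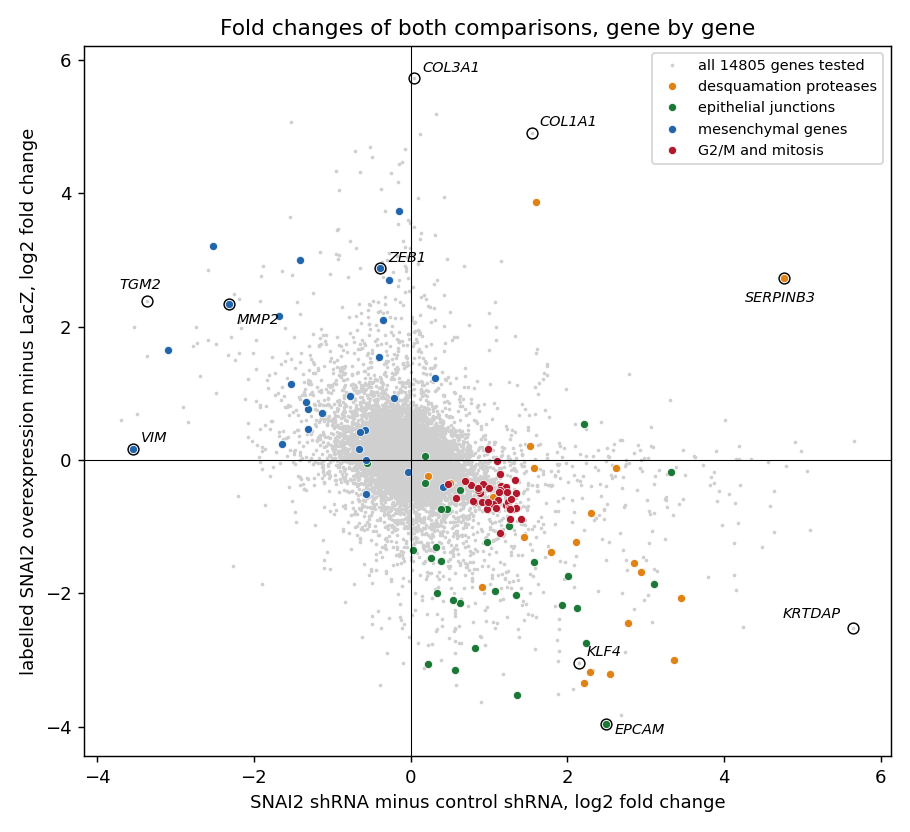
Log2 fold change with SNAI2 shRNA (horizontal) against that in the arrays labelled SNAI2 overexpression (vertical), 1 dot per gene for 14805 genes, with members of 4 lists in colour and 10 genes circled. Junction genes, desquamation proteases and G2/M genes lie mostly at the lower right and mesenchymal genes mostly at the upper left (r = -0.356 over all genes).

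**Figure D3:**
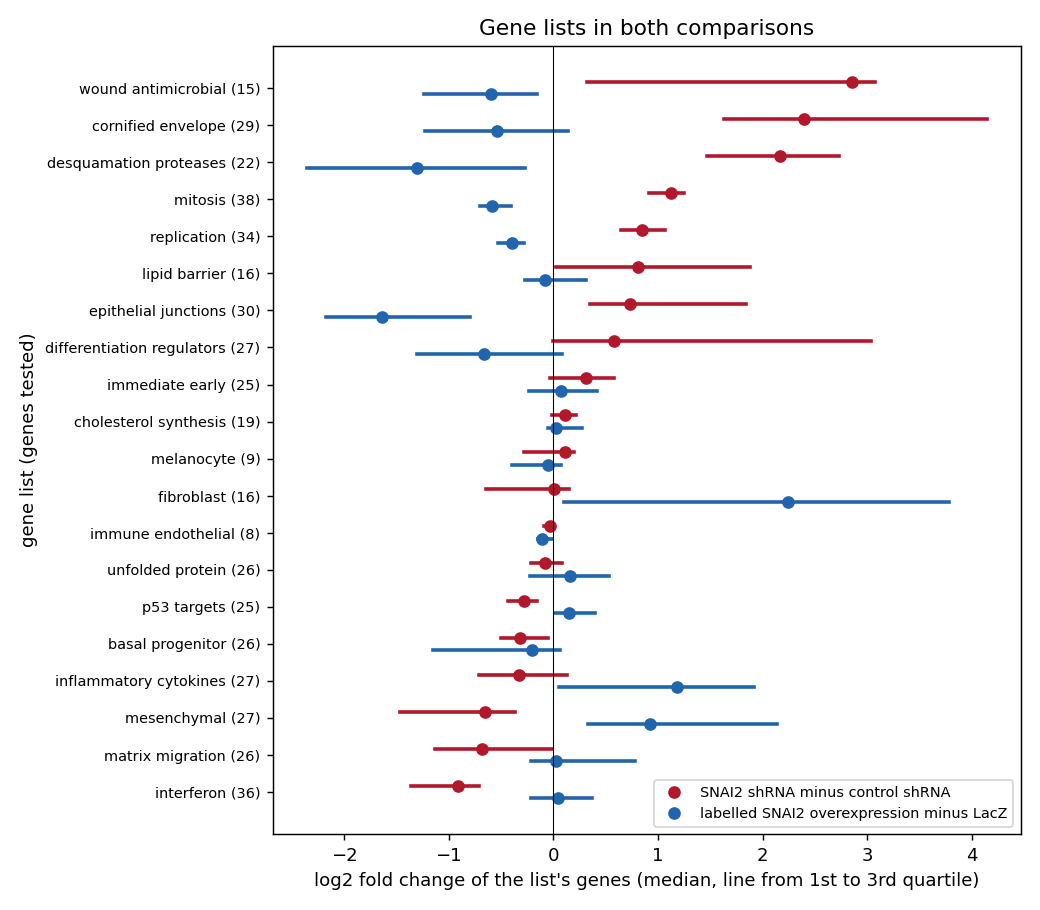
Median log2 fold change of each of the 20 lists, with a line between the quartiles of its genes, for SNAI2 shRNA against control (red) and the arrays labelled SNAI2 overexpression against LacZ (blue). The number of genes tested stands beside each list; the G2/M list has medians of 1.12 and -0.58 and the mesenchymal list -0.65 and 0.93.

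The LacZ and control shRNA arrays were compared to size the difference between the control cultures, which includes vector, culture and array scale. GLDC, the glycine decarboxylase, was higher in LacZ arrays by 2.76 relative to the median of all genes, the muscarinic receptor CHRM3 by 2.62, the zinc transporter SLC39A2 by 2.24, LYPD3 by 2.23 and NDN by 2.17. FIBIN was lower by 3.11 on that measure, HSD11B1, which converts cortisone to cortisol, by 2.85, the calcium-binding protein CALB1 by 2.48 and GSTM3 by 2.48. SLC39A2 in control shRNA and CALB1 in LacZ arrays had mean signals under 16, so the size and rank of their differences depend on the pseudocount. Without sets that can match several transcripts, GSTM3 turned to 0.34 before subtracting that median (adjusted p = 0.00216). The median of all genes was 0.78 in that fit, so GSTM3 stayed below it. The median of all genes was 0.81 higher in LacZ arrays, and 14340 genes passed on the deposited scale, 14198 upward and 142 downward. After quantile normalization 6088 passed, 2360 upward and 3728 downward; after median centring 7251, 5869 and 1382; and after scaling by the trimmed mean 6438, 2875 and 3563. On the deposited scale, which differs between these groups, camera called 11 of 20 lists, and with an estimated correlation 0, with 4 at an unadjusted p under 0.05. Fry called all 20 on that scale. The median difference of all genes grew with signal level, from 0.70 without the level filter to 0.86 when more dim genes were left out. List calls between the controls can therefore reflect signal level, and they were not repeated on a common scale.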

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

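The tests of exchanged labels, of the probe set, of fibroblasts and of dividing control cells were chosen only after the result was seen; the test of array scaling was not.

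The response to the SNAI2 shRNA differed from that of the arrays labelled SNAI2 overexpression for 7960 of 14805 genes in the test of the difference itself, which is why this result was singled out. Of these, 3744 were higher with the shRNA relative to those arrays and 4216 lower. Opposite changes add up in this test, and a change in a single comparison can also pass it. The count therefore does not stand apart from the counts of both comparisons. Probe sets that name no gene or several genes, which the gene tests did not use, also responded. Of 10141 tested, 75 were at least 2-fold higher and 57 lower with SNAI2 shRNA than in its control. In the arrays labelled SNAI2 overexpression, 86 were higher and 124 lower than in LacZ arrays.

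The SNAI2 signal was lower, not higher, in the arrays labelled SNAI2 overexpression. An exchange of the LacZ and SNAI2 labels is argued against by the control shRNA arrays, which carry no SNAI2 construct: for 85.9% of the 1040 genes that differed at least 2-fold between these groups they lay nearer to the LacZ arrays, and single control arrays gave 87.1% and 85.7%. That the probe set does not read the construct's transcript stays open, since 0 of the 2 arrays labelled SNAI2 overexpression lay above either LacZ array and the probe set's position is not known here. In that case the lower signal would be that of the cells' own SNAI2 transcript, which could be lower in the presence of the construct. This biological explanation was not tested.

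The mesenchymal and fibroblast marker lists were higher and the junction list lower in the arrays labelled SNAI2 overexpression by camera at its preset correlation, and none passed with an estimated correlation (adjusted p = 0.056, 0.056 and 0.154). Fibroblasts in these cultures, as the whole cause of the lower junction genes, are argued against only by 3 genes of the basal list. The keratinocyte cadherin CDH3 differed by -0.07 (SE 0.0578), KRT14 by -0.05 (SE 0.053) and KRT5 by -0.50 (SE 0.0562). Dilution alike would give about the median junction change of -1.64. These 3 genes were picked after the result was seen, and other members fell further than that median. KRT15 differed by -2.723, BCAM by -2.435 and SOX7 by -1.927. Of the 26 members 13 fell, 5 rose and 8 did not pass, so the list does not settle this explanation. The basal list as a whole had a median of -0.21, but it includes POSTN, which is also a fibroblast marker and rose by 5.07. Fibroblasts as the source of the higher fibroblast markers, 5 collagen genes among them, cannot be told apart from a change in the keratinocytes themselves, since 11 of 16 fibroblast markers rose while LUM, DPT, COL6A2 and FAP did not pass and PRRX1 fell, which speaks against fibroblasts rich in all 16, and no fibroblast arrays give the levels their share would need. A response of the keratinocytes to the construct, the biological explanation the design gives, also stays open.

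G2/M genes and late differentiation genes were both higher in the SNAI2 shRNA arrays, although differentiating keratinocytes are known to leave the cell cycle. Array scaling is argued against, since the median change of the G2/M list was 1.12 on the deposited scale, 1.08 after quantile normalization and 1.10 after median centring. A control shRNA culture with fewer dividing cells than other control cultures stays open. The G2/M list lay 0.70 higher in LacZ than in control shRNA arrays relative to all genes, less than the rise of 1.12. It lay 0.42 higher in SNAI2 shRNA than in LacZ arrays on that measure. Vector, culture, experiment and array scale differ between these groups. Both values come from the deposited scale, where subtracting the median of all genes need not remove the scale difference. An effect of SNAI2 on both gene groups, or on different cells of a mixed culture, also stays open and was not tested.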

How the results depend on the processing

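Trimmed mean scaling and the crossed pairing were the tests chosen only after the result was seen. The counts of changed genes in both perturbations, of different responses and of opposite changes stayed within 1.5 times their main value under quantile normalization, median centring, trimmed mean scaling, both filters, the mean of probe sets, sets without shared probes, pseudocounts 1 and 64, and every left-out array. The correlation across genes and the fall of SNAI2 in both comparisons did so too, and they kept their direction. The same held for the values run under other eBayes priors, which leave out the correlation, and under the fits to 4 arrays, which leave out the correlation and the different responses. The exceptions follow from how an alternative counts: testing every probe set gave 10702, 12175 and 13908 for the shRNA, the arrays labelled SNAI2 overexpression and their difference, and 29273 for LacZ against control shRNA, and asking for 2-fold gave 871, 1040, 2341 and 3763, with 257 genes opposite. An adjusted p under 0.01 left 1974 opposite. The balance of rises and falls in the arrays labelled SNAI2 overexpression was less stable than the total. In the main fit more genes rose than fell there (3739 and 3439). More fell than rose after median centring (3755 and 3460) and when more dim genes were left out (2897 and 2886). The balance also turned without replicate 2 labelled SNAI2 overexpression. LacZ against control shRNA depended on scale, with 6088 genes after quantile normalization, 7251 after median centring and 6438 after trimmed mean scaling, against 14340. With an estimated correlation camera called 0 lists for the shRNA and 0 for the arrays labelled SNAI2 overexpression, against 14 and 12. For the mesenchymal and fibroblast lists the estimates, 0.00859 and -0.0312, lay below the preset 0.01. A correlation above the preset one therefore does not explain their lost calls. Other lists had estimates up to 0.585 (G2/M). The cause was otherwise not tested. The 226 results on named genes in both perturbations were computed 4914 times, alternatives only: 4819 kept direction and side of the threshold, 80 lost the call, 9 gained it and 6 turned. Turned were SOX10 in the arrays labelled SNAI2 overexpression at 0.24 (mean of probe sets) and, without sets with shared probes, GINS2 at -0.049 and ARHGEF40 at 0.118 with the shRNA, SMPD1 at -0.528 in the arrays labelled SNAI2 overexpression and, in addition to these 6, GSTM3 at 0.336 between controls. The value of GSTM3 turned only on the deposited scale and stayed below the median of all genes, 0.782 in that fit. Without sets with shared probes another probe set stood for the gene, and the cause of the difference was not tested. KRT14 with the shRNA, never past the threshold, made up the rest and ranged from -0.02 to 0.018 over the left-out arrays. Replicate numbers were not taken as pairing: deviations of same-numbered arrays correlated at 0.207 for the shRNA and -0.108 for the LacZ and SNAI2 overexpression arrays, and the replicate block gave 6284 and 6964 changed genes, against 6553 and 7178. With the latter arrays crossed, it gave 6854 and 7476. A left-out array leaves a group with 1 array, which is then assumed to vary like the others. Background correction was not run. From 42.8% to 43.9% of probe sets on shRNA arrays and 26.8% to 27.5% on the others lay under a signal of 16, where changes are compressed.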

Other observations

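The groupings of genes below and the tests of these genes with arrays left out were chosen only after the result was seen, and no grouping was tested as a group of its own. In the arrays labelled SNAI2 overexpression, the list of unfolded protein genes split: 11 of 26 members rose, 8 fell and 7 did not pass, and the list did not pass by camera (adjusted p = 0.575). Higher than in LacZ arrays were CRELD2 by 0.82 (SE 0.0643), SEL1L by 0.76, SDF2L1 by 0.70, DNAJB9 by 0.62, PPP1R15A by 0.55, MANF, HYOU1, DNAJC3, PDIA4, CALR and the chaperone HSPA5 by 0.32 (SE 0.0517, 10410 ± 28.6 against 8351 ± 5.94, SD, n = 2). Lower were CHAC1 by 1.17 (SE 0.0937), DDIT4 by 0.87, the asparagine synthetase ASNS by 0.87 (SE 0.0568, 2266 ± 60.6 against 4144 ± 137), PSAT1 by 0.70, CEBPG by 0.66, VLDLR, TRIB3 and ATF4. HSP90B1, HERPUD1, EDEM1, XBP1, DDIT3, SLC7A11 and PHGDH did not pass. Left-out arrays ended the calls of PPP1R15A (LacZ replicate 2 or either array labelled SNAI2 overexpression, adjusted p = 0.109 to 0.175), TRIB3 (replicate 1 of LacZ or of the arrays labelled SNAI2 overexpression, adjusted p = 0.0818 and 0.0691) and ATF4 (either LacZ array, adjusted p = 0.0927 and 0.0507). They brought DDIT3 and HSP90B1 (either control shRNA array, adjusted p = 0.0489 and 0.0202) and PHGDH (LacZ replicate 2, adjusted p = 0.0484) past the threshold. With SNAI2 shRNA, 9 members fell, HERPUD1 by 0.65, and 3 rose, counts that were 4 and 0 without control shRNA replicate 1 and 6 and 1 without SNAI2 shRNA replicate 2.

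Of 10 genes of the Notch pathway in the list of differentiation regulators, 4 rose with SNAI2 shRNA, 2 fell and 4 did not pass. The receptor NOTCH3 rose by 3.87 (SE 0.089), from 13 ± 2.89 to 409 ± 29.8 (SD, n = 2), HES5 by 2.93 (SE 0.0929), HEY1 by 0.42 and NOTCH2 by 0.37, while the ligand JAG1 fell by 0.56 (SE 0.0571) and NOTCH1 by 0.26. NOTCH3 and HES5 had mean signals under 16 in the control, so the size of their rise depends on the pseudocount. HES1, RBPJ, JAG2 and DLL1 did not pass, though HES1 did without control shRNA replicate 1 (1.155, adjusted p = 0.00908). In the arrays labelled SNAI2 overexpression, RBPJ and HEY1 rose by 0.735 and 0.183, the ligands DLL1 and JAG2 fell by 1.82 and 1.45, HES1 by 1.12 (adjusted p = 0.0275) and NOTCH1 by 0.72, and NOTCH2, NOTCH3, HES5 and JAG1 did not pass. The call of HES1 was lost without any 1 of the LacZ arrays or those labelled SNAI2 overexpression (adjusted p = 0.0829 to 0.117), and that of HEY1 without any 1 of these or of the control shRNA arrays (adjusted p = 0.0647 to 0.147).

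Array controls gave the following values. The 24 poly-A spike-in probe sets were 1.8-fold lower in the arrays labelled SNAI2 overexpression than in LacZ arrays and differed by 0.05 on the log2 scale between the shRNA groups. The first difference, -0.85, was larger in size than the median absolute change of the genes called in that comparison (0.42). Gene changes were not rescaled to these spike-ins. The 18 hybridisation spike-in probe sets differed by -0.01 in the shRNA and 0.05 in the construct experiment. The 3 probe sets for 18S ribosomal RNA were 1.37-fold lower in the arrays labelled SNAI2 overexpression than in LacZ arrays (-0.46), and differed by -0.10 in the shRNA experiment. They were higher in replicate 2 than in replicate 1 in all 4 groups, by 0.30 to 0.60. The signal of the 3' probe set of beta-actin was 1.12 to 1.55 times that of the 5' probe set over the 8 arrays, highest in SNAI2 shRNA replicate 2.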
